A study of Mus musculus with 14 samples.

How the data were processed

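The 14 libraries hold RNA of islet cells of male mice aged 7 months, 7 of beta-galactosidase-positive and 7 of beta-galactosidase-negative cells. The cells were sorted by flow cytometry on the activity of the enzyme at acidic pH. Per the labels' protocols, RNA was extracted with a kit for small cell numbers, polyadenylated RNA was selected with oligo(dT) beads, and libraries were made with a directional (strand-marking) kit. Per the series' design text they were sequenced as single reads on a HiSeq instrument. Per the submitters' processing notes, Subread placed the reads on GRCm38 and featureCounts counted them per gene. Their versions, the annotation, the strand setting and the treatment of reads that match several genes were not given in the sources used here. The deposited values are raw read counts per gene, whole numbers that sum to a different total in each library. Because the strand setting is not known, overlapping and antisense genes cannot be told apart, and genes with near-identical copies are uncertain.

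The deposited count table held 52459 genes, named by symbol, and 14 columns, each matched to a sample by the column name in its label. Every gene had a name, and 31875 genes had at least 1 count. Of the symbols, 91.5% matched 1 gene of the GENCODE M21 annotation, from which coordinates on GRCm38 were taken. The share of all counts in the 20 genes with the most reads was 20.83 ± 1.62% in negative and 18.53 ± 0.81% in positive libraries (SD, n = 7 each). The lowest chi-square per degree of freedom between 2 replicates of a group, over genes of at least 20 counts, was 5.36, so no 2 libraries agreed within sampling noise, and all 14 were counted as separate samples. The labels do not say whether the numbered libraries came from separate animals, so p-values measure the spread between these libraries, which may be partly technical.

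Groups were compared with edgeR 4.0.16 in R 4.3.3. Genes with too few counts were removed by filterByExpr, leaving 16350, and library sizes were scaled by TMM factors (0.969 to 1.03). Dispersions were estimated robustly (common biological coefficient of variation 0.198), and the quasi-likelihood F-test was applied with group as the only term. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called, and standard errors were taken from the F statistic and the log2 fold change. CPM were computed by edgeR from the TMM-scaled library sizes, and log2 CPM for scores and principal components used a prior count of 2. Tests are two-sided. Counts were also simulated from the real means and library sizes, with 200 genes changed in 7 against 7 libraries and 16189 genes tested. A list of 30 further genes was shifted as well. Of the 200, 49.5% of the 1.5-fold and 80.4% of the 2-fold changes were recovered, and 2.7% of all calls were unchanged genes. Each count was drawn independently, without pairs or a varying mix of cells, so the rates in the real data may differ.

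The replicate numbers are shared by the groups, and whether they pair the libraries was checked before the blocked calls were compared. Deviations from the group means of libraries with the same number correlated across genes with 0.2 to 0.54 in all 7 pairs, against a median of −0.13 for different numbers. The numbers were therefore taken to pair the libraries. This comes from the numbers in the titles and from these correlations, since the labels do not say that a number marks the same animals. The fit with the replicate number as a block is given beside a list where it changes the list's call or moves its count of members by more than 1.5 times. Genes called only with the block are otherwise given as counts. Where no setting is named, calls come from the fit without the block, so a gene not called may still differ within pairs.

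Before the data were examined, 42 gene lists were fixed. They cover markers of alpha, delta, PP, acinar, ductal, endothelial, stellate, pericyte and fibroblast, macrophage and dendritic, lymphocyte, neutrophil and mast, Schwann, red blood and fat cells, beta cell identity, disallowed and progenitor genes, senescence effectors, beta cell aging markers, and secretory phenotype factors. They also cover pathways of lysosomes, autophagy, protein folding, p53, antioxidants, the cell cycle, immediate early genes, interferon, NF-kappaB, apoptosis, glycolysis, the TCA cycle, cholesterol, insulin and IGF, TGF-beta, cilia, ribosomes, mitochondria, the proteasome, collagens and histones. The 36 lists with at least 5 measured genes were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over these 36. At an estimated correlation none of the 22 lists called was called without the block. Calls of members are counted over all genes tested and adjusted over the list alone. Lists share members: 10 of the 39 secretory phenotype factors, 8 of the 23 disallowed genes, 9 of the 25 senescence effectors and 8 of the 27 p53 targets stand in another list too. Another 5 lists were added after the data were seen.

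Genes are named by a rule fixed before the data were examined: 12 genes whatever their result (Glb1, Cdkn2a, Cdkn1a, Trp53, Igf1r, Ins1, Ins2, Mafa, Pdx1, Gcg, Sst and Ppy), the 8 largest rises and 8 largest falls among called genes of at least 3 in average log2 CPM, and for each list described up to 4 members with the smallest p, up to 2 called members of the opposite direction, and for cell type lists up to 2 members with the highest mean CPM. Other members that are named stand there to complete a count and were chosen after their values were seen. Some genes that this rule names are not reported here.

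The alternatives were the block, DESeq2 1.42.0 with its own size factors and Wald test, DESeq2 size factors or library size alone in edgeR, limma voom with sample weights, no filter on low counts, at least 1 CPM in at least 7 samples, no robust estimation, library sizes without the 20 highest genes, fry in place of camera, an estimated correlation, and leaving out each library in turn. After the data were seen, 3 more were added. These were macrophage and endothelial marker scores (the mean log2 CPM of each list) as covariates, the fit without the 4 libraries numbered 6 and 7, and camera with both the block and an estimated correlation.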

Results

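Gene expression was measured by RNA sequencing in cells of dispersed pancreatic islets from 7-month-old male C57BL/6J mice, a standard inbred strain. The cells had been parted by fluorescence-activated sorting on acidic beta-galactosidase activity. This lysosomal enzyme activity is widely used as a marker of cellular senescence, a lasting arrest of the cell cycle. There were 7 libraries of beta-galactosidase-positive cells (below, positive) and 7 of beta-galactosidase-negative cells (negative), numbered 1 to 7 in both groups. Total counts ranged from 11060144 to 23045934 reads in the negative and from 15585779 to 24577025 in the positive libraries. The series title places the samples in a study of beta cell aging in diabetes, so the comparison asked which transcripts set apart islet cells that carried this senescence marker from those that did not. The first principal component of log2 expression held 60.1% of the variance and separated the positive from the negative libraries.

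Genes known from macrophages and endothelial cells rose strongly in positive libraries. The macrophage genes C1qb (log2 fold change 6.75 ± 0.93, SE, adjusted p = 0.000372), Mpeg1 (6.66 ± 0.88, adjusted p = 0.000309) and Lyz2 (6.38 ± 0.77, adjusted p = 0.00017) and the endothelial gene Kdr, the receptor for vascular endothelial growth factor (5.38 ± 0.72, adjusted p = 0.000329), rose in the positive library of all 7 pairs. Many secreted factors of the senescence-associated secretory phenotype rose with them, among them Igfbp5, Lamb1, Ccl5 and Tnf. The beta cell genes Trpm5, Tmem27, Neurod1 and Mlxipl fell by 0.35 to 0.68 on the log2 scale. The calls of Neurod1 and Mlxipl were near the threshold and were lost when single libraries were left out. Of 28 acinar markers 7 fell, among them the digestive enzyme Pnlip, by 3.56. With the replicate number as a block, 22 of the 28 fell. Of 48 beta cell genes, 25 fell and 2 rose with the block. The senescence genes Cdkn2a and Glb1 gave log2 fold changes of 0.03 and 0.04 and were not called.

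Of 16350 genes tested, 1313 were called between the groups by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1047 higher and 266 lower in positive cells. With the replicate number as a block, 3200 genes were called, 1930 higher and 1270 lower. Among the genes of at least 3 in average log2 CPM, the largest rise was that of Cyp1a1, a cytochrome P450 enzyme induced through the aryl hydrocarbon receptor (chromosome 9, 57687928 to 57703824, GRCm38), from 0.555 ± 0.714 to 74.2 ± 41.1 CPM (SD, n = 7 each), a log2 fold change of 6.91 ± 0.59 (SE, adjusted p = 2.6e-05). The next 7 rises were C1qb, Mpeg1, Clec7a (6.47), Lyz2 (chromosome 10, 117277331 to 117282321), Cybb (6.29), Acp5 (6.17) and Lilr4b (6.06), all genes known from macrophages and other myeloid cells. Their negative levels rested on few reads, with 19 counts of C1qb, 22 of Clec7a and 28 of Acp5 over all 7 negative libraries, so the size of these folds is uncertain. Lilr4b has a near-identical neighbour, and how reads were shared between them is uncertain. The largest falls were those of the acinar enzymes Clps (log2 fold change −3.59 ± 0.76), Pnlip (−3.56 ± 0.79), Cpb1 (−3.22 ± 0.80) and Cel (−2.79 ± 0.73). They were followed by Aqp4, a water channel (−1.05 ± 0.21), Rgs16, a regulator of G protein signalling (−1.04 ± 0.14), Barhl1, a homeobox factor (−0.80 ± 0.14), and 6330403K07Rik (−0.79 ± 0.15). All 8 were lower in the positive library of all 7 pairs. The call of Cel was lost without negative 1, 2 or 5 or positive 2, 4, 6 or 7 (adjusted p 0.0572 to 0.0753), and that of Cpb1 without negative 1 (0.056), positive 6 (0.0535) or positive 7 (0.0565).

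The count of lower genes depended on single libraries. It was 616 without negative 3, 140 without positive 6, 160 without positive 3 and 162 without positive 7, against 266 with all 14. Without the 4 libraries numbered 6 and 7, which carried the most macrophage and endothelial RNA in their groups, 581 genes were called, 536 higher and 45 lower. This fit was added after the data were seen. With the macrophage and endothelial marker scores as covariates, also added after the data were seen, 1 gene was called, Jun, and 484 had an unadjusted p below 0.05. Without the scores 3457 did.

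Markers of endothelial cells and of macrophages and dendritic cells rose almost without exception. Of 27 measured macrophage and dendritic cell markers, 27 rose (median log2 fold change 5.91; 27 adjusted over the list alone), and of 20 endothelial markers, 19 rose (median 4.85; 20 adjusted over the list alone). Lyz2 went from 0.316 ± 0.327 to 28.6 ± 28.2 CPM, and Apoe, the marker with the highest mean CPM of its list, from 7.48 ± 2.84 to 158 ± 154 CPM (SD, n = 7 each). Among endothelial genes Esm1 rose from 5.12 ± 7.07 to 193 ± 102 CPM and Kdr from 3.20 ± 4.37 to 142 ± 70.9 CPM. Egfl7, Cd34 and Ptprb rose with log2 fold changes of 3.76, 4.58 and 4.65. Both lists rose against other genes in camera, a competitive gene set test (adjusted p = 2.91e-36 and 2.60e-39), but not with an estimated correlation (adjusted p = 0.116 for each). With both the replicate number as a block and an estimated correlation, the adjusted p was 0.0145 for each list. In negative cells, 6 of the 27 macrophage and 11 of the 20 endothelial markers reached a mean of 1 CPM.

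**Figure D1:**
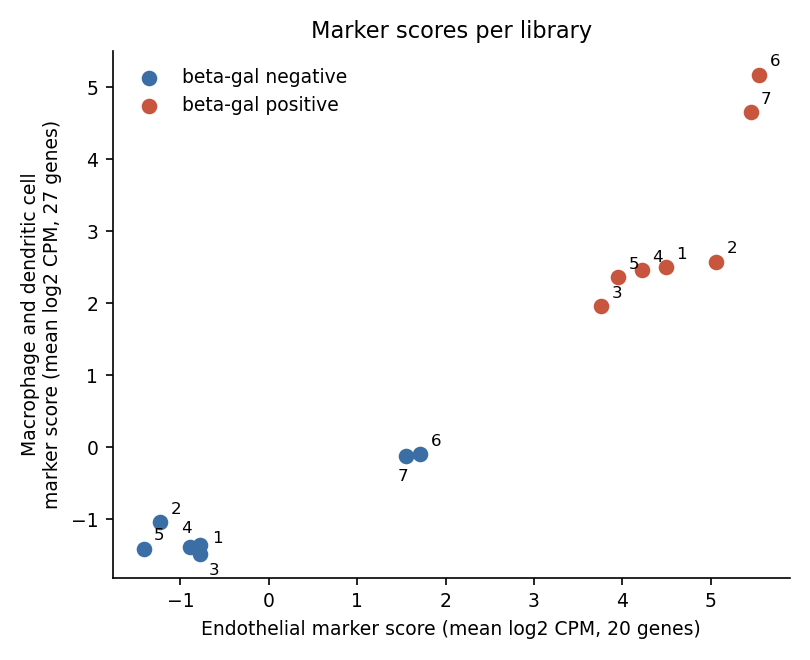
Mean log2 CPM of 20 endothelial markers (x axis) against that of 27 macrophage and dendritic cell markers (y axis) in each of the 14 libraries, with the replicate number beside each point. Positive libraries lay above every negative library on both axes, and the libraries numbered 6 and 7 had the highest macrophage scores within their groups, 5.17 and 4.66 in positive and −0.09 and −0.12 in negative cells.

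Of 21 markers of stellate cells, pericytes and fibroblasts, 6 rose and 15 were not called (6 adjusted over the list alone). Those that rose were Abcc9 (log2 fold change 3.76), Rgs5 (4.02), Notch3 (2.87), Des (2.56), Mgp (3.15) and Pdgfrb (2.42; lost without any library but negative 3, 0.0533 to 0.0947), most of them known from pericytes, the contractile cells that wrap capillaries. The fibroblast collagen Col3a1 was not called (adjusted p = 0.307), at 100 ± 234 CPM in negative and 20.6 ± 28.2 CPM in positive cells (SD, n = 7 each). Negative 3 alone had 631 CPM, and the log2 fold change of Col3a1 went from −2.27 to 0.795 without it. The abundant marker Gsn had a log2 fold change of 0.02. The list rose in camera (adjusted p = 0.000497) but not with an estimated correlation (adjusted p = 0.486), while its median was 0.02 and its mean 0.38. Of 3 lymphocyte markers measured, Cd79b rose and Cd79a fell (log2 fold changes 1.37 and −1.45). Cd79b was near the threshold (adjusted p = 0.0263) and lost its call without negative 1, 2, 4, 6 or 7 or positive 1, 3 or 7 (0.05 to 0.0598). Of 2 adipocyte markers, Fabp4, which endothelial cells also express, rose (4.90), and Lpl fell (−0.50). Of 3 Schwann cell markers none was called (1 lower adjusted over the list alone; 1 called with the block). Neither the single neutrophil and mast cell marker measured, Kit (0.89), nor the single red blood cell marker, Bpgm (0.18), was called over all genes. Of 16 ductal markers 1 rose, Anxa3 (3.70), with 4 called under the block, and the list did not change (adjusted p = 0.694).

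Of 39 measured secretory phenotype factors, 25 rose, 0 fell and 14 were not called (28 higher adjusted over the list alone), with a median log2 fold change of 2.04. Igfbp5, a binding protein of insulin-like growth factors, rose from 13.7 ± 6.11 to 229 ± 76.9 CPM, and Lamb1, a laminin chain, from 3.48 ± 2.98 to 56.2 ± 26.6 CPM (SD, n = 7 each). The chemokine Ccl5 and the cytokine Tnf had log2 fold changes of 6.39 ± 0.90 and 6.25 ± 0.90 (SE), from 10 and 20 counts over the 7 negative libraries. All of these genes were higher in the positive library of all 7 pairs. The list rose in camera (adjusted p = 4.97e-22) but not with an estimated correlation (adjusted p = 0.116). Macrophage and endothelial markers rose in the same libraries by medians of 5.91 and 4.85. With their scores as covariates the list's direction in camera turned, to lower (adjusted p = 0.484, median −0.02), with 0 members called. That fit called 1 gene in all, and the scores accounted for 86.7% of the variance of the group label. Its group term is poorly determined, so it cannot decide whether RNA of such cells raised the list. Targets of NF-kappaB, a transcription factor of inflammation, overlapped with this list. Of these, 5 of 19 rose, Tnfaip2 (4.17), Icam1 (3.45), Cxcl2 (5.49), Vcam1 (3.09) and Cxcl1 (2.51; lost without negative 1, 2, 4, 5, 6 or 7 or positive 1, 6 or 7, 0.0575 to 0.0968), with 6 adjusted over the list alone. That list was called in camera (adjusted p = 0.0131), not with an estimated correlation (adjusted p = 0.468) and not without negative 1 (adjusted p = 0.11).

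**Figure D2:**
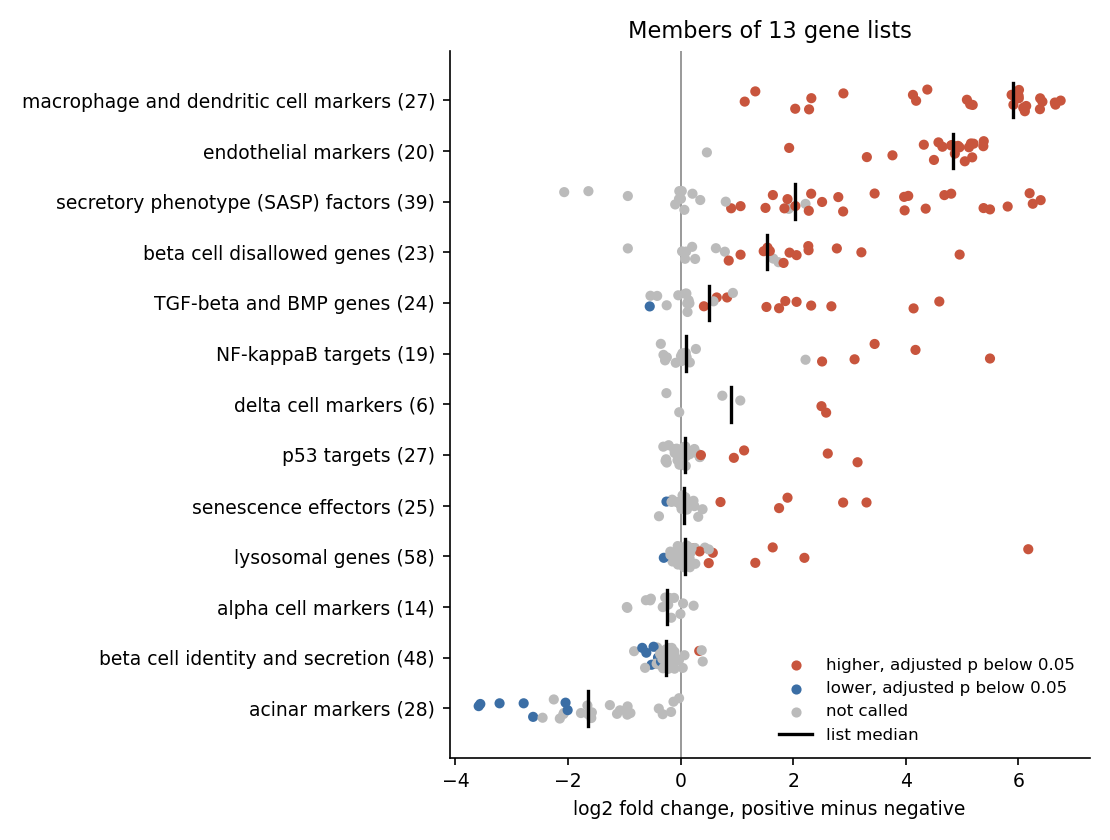
Log2 fold change, positive minus negative, of each measured member (points) of 13 gene lists, with the number of members in brackets and the list median as a black bar. Colour marks calls at an adjusted p below 0.05. Medians ran from 5.91 for macrophage and dendritic cell markers to −1.65 for acinar markers, while senescence effectors, p53 targets and lysosomal genes had medians of 0.06 to 0.08.

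Of 25 senescence effectors, 5 rose, 1 fell and 19 were not called (7 higher and 1 lower adjusted over the list alone). Among those that rose were Ets1 (log2 fold change 3.30), Plaur (2.89), Id1 (1.75) and Cdkn1c (0.71). Ets1 and Id1 are transcription regulators well known from endothelial cells, and Plaur is the urokinase receptor. Trp53bp1, a DNA damage response protein, fell from 155 ± 14.4 to 130 ± 8.86 CPM (SD, n = 7 each; log2 fold change −0.25 ± 0.07, SE, adjusted p = 0.0262; 0.0539 without positive 3). The list was called higher in camera (adjusted p = 0.028, with a median of 0.06), and not called with an estimated correlation (adjusted p = 0.315), with the block (adjusted p = 0.151, 10 members called), or without negative 1 (0.0549), negative 7 (0.05001) or the 4 libraries numbered 6 and 7 (0.222). The call of Cdkn1c (adjusted p = 0.0488) was lost without any library but negative 4 and positive 1 (0.0503 to 0.117). Cdkn2a, which encodes the cell cycle inhibitor p16 (chromosome 4, 89274471 to 89294653), was low, at 0.763 ± 0.224 CPM in negative and 0.783 ± 0.166 CPM in positive cells, a log2 fold change of 0.03 ± 0.21 (SE, adjusted p = 0.952, higher in 4 of 7 pairs). Counts are per gene, so the transcripts of Cdkn2a were pooled and that of p16 alone was not measured. Glb1, which encodes lysosomal beta-galactosidase (chromosome 9, 114401076 to 114474898), had 17.5 ± 1.88 and 18.1 ± 0.912 CPM (log2 fold change 0.04 ± 0.07, adjusted p = 0.777), with a 95% interval of −0.11 to 0.19. Cdkn1a, the inhibitor p21, had 263 ± 71.7 and 327 ± 23.9 CPM (0.31 ± 0.15, adjusted p = 0.239; 0.0384 with the block, higher in 6 of 7 pairs). Trp53, which encodes p53, had a log2 fold change of 0.08 ± 0.13 (adjusted p = 0.761).

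Of 6 measured beta cell aging markers, 1 fell, Trp53bp1, and 5 were not called (0 higher and 1 lower adjusted over the list alone), and the list did not change in camera (adjusted p = 0.672). Igf1r, the receptor of insulin-like growth factor 1, was at 473 ± 106 CPM in negative and 592 ± 102 CPM in positive cells (log2 fold change 0.32 ± 0.14, SE, adjusted p = 0.194). It was higher in the positive library of all 7 pairs, with an adjusted p of 0.00125 under the block. Bambi, a decoy receptor of TGF-beta, had −0.42 ± 0.17 (adjusted p = 0.164; 0.00253 with the block, lower in all 7 pairs), so that 4 of the 6 were called under the block. Of 27 p53 targets 5 rose and 0 fell (6 higher and 1 lower adjusted over the list alone), with Tnfrsf10b, a death receptor, at 2.61, Pmaip1, a pro-apoptotic protein, at 3.14, Ckap2 at 1.13, Plk2 at 0.94 and Perp at 0.36 (lost without negative 1, 2, 5 or 6 or positive 1 or 7, 0.0504 to 0.0653). Pmaip1 was at 13.5 and 11.8 CPM in positive 6 and 7, the libraries with the highest macrophage scores, and at 2.92 to 5.6 CPM in the other positive libraries. Their list was called in camera (adjusted p = 0.0393) but not with an estimated correlation (0.355 as adjusted p), with the block (adjusted p = 0.231, 10 members called), or without negative 1 (0.0549), 6 (0.0888) or 7 (0.0885) or positive 5 (0.0582), nor without all 4 libraries numbered 6 and 7 (0.382). It was also called with fry (0.00366), which tests a list against no change and not against other genes. With the marker scores as covariates camera still called it higher (0.012, 0 members called), in a fit whose group term is poorly determined.

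**Figure D3:**
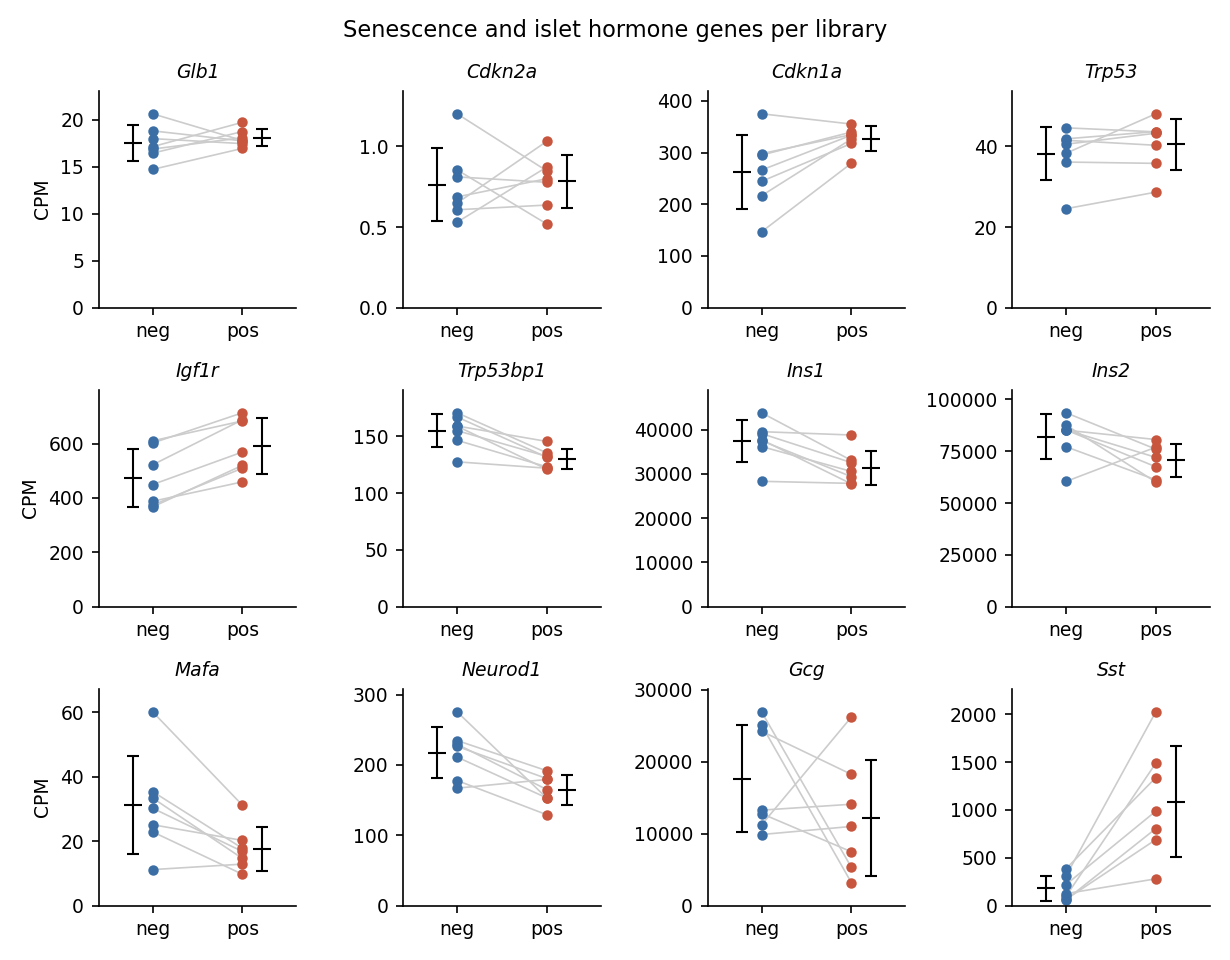
CPM of 12 genes in the 7 negative (blue) and 7 positive (red) libraries, with lines joining libraries of the same number and black bars for the mean ± SD. Each panel has its own axis, starting at 0. Glb1 and Cdkn2a overlapped between the groups, Igf1r rose and Trp53bp1 fell in all 7 pairs, and Sst rose in all 7.

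Of 48 genes of beta cell identity and insulin secretion, 6 fell, 1 rose and 41 were not called (9 lower and 1 higher adjusted over the list alone), with a median log2 fold change of −0.25. Trpm5, a calcium-activated cation channel of glucose-stimulated secretion, went from 66.6 ± 9.43 to 47.7 ± 6.69 CPM (SD, n = 7 each; −0.48 ± 0.10, SE, adjusted p = 0.00615), and Tmem27 from 406 ± 24.8 to 319 ± 43.6 CPM (−0.35 ± 0.08, adjusted p = 0.0146), both lower in the positive library of all 7 pairs. The transcription factors Neurod1 (−0.40 ± 0.11) and Mlxipl (−0.68 ± 0.19) also fell, as did Gipr (−0.52) and Insrr (−0.61), whereas Stx1a, a protein of vesicle fusion, rose (0.33 ± 0.10). Calls other than those of Trpm5 and Tmem27 were near the threshold, with adjusted p of 0.0303 for Neurod1, 0.0345 for Mlxipl, 0.0471 for Stx1a, 0.0421 for Gipr and 0.0448 for Insrr, and rested on single libraries. The call of Neurod1 was lost without negative 2, 4 or 5 or positive 2, 6 or 7 (0.0517 to 0.0624). That of Mlxipl was lost without negative 1, 2, 4 or 5 or positive 3 or 6 (0.0581 to 0.0688), and that of Stx1a without any library but negative 3 and positive 1 and 4 (0.0536 to 0.112). Gipr lost its call without any library but negative 3 and positive 1 and 5 (0.0545 to 0.0846), and Insrr without any but negative 3 and positive 4, 5 and 7 (0.0529 to 0.0917). The list fell in camera (adjusted p = 2.23e-08) but not with an estimated correlation (adjusted p = 0.364). With the block, 25 members fell and 2 rose. Those called only then included Mafa (log2 fold change −0.83 ± 0.32, adjusted p = 0.143; 0.0158 with the block), Pdx1 (−0.42 ± 0.36, adjusted p = 0.557; 0.028 with the block; −0.03 without negative 1 and −0.72 without positive 1) and Ins1 (−0.25 ± 0.10, adjusted p = 0.165; 0.0447 with the block). Without negative 3, Mafa and Ins1 were called without the block too (adjusted p = 0.0298 and 0.0295). Ins2, the most abundant transcript of the list, was at 82080 ± 10690 and 70640 ± 7962 CPM (−0.22 ± 0.11, adjusted p = 0.261; 0.176 with the block). Ins1 and Ins2 are close paralogs, so reads of 50 bases could be split between them. In the same libraries, macrophage and endothelial markers were higher by medians of 5.91 and 4.85.

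Of 23 beta cell disallowed genes, which are kept low in beta cells and are expressed in most other cells, 13 rose, 0 fell and 10 were not called (15 higher adjusted over the list alone; median 1.54). Arhgdib, a gene known from blood cells, had a log2 fold change of 4.96 ± 0.52, Nfib 3.21 ± 0.52, the repressor of neuronal genes Rest 2.27 ± 0.32 and the signal transducer Smad3 2.06 ± 0.23 (SE), each higher in all 7 pairs. The list rose in camera (adjusted p = 6.93e-16) but not with an estimated correlation (adjusted p = 0.116), and the macrophage and endothelial markers given above rose in the same libraries. Of 9 progenitor genes, 1 rose, Hes1, a target of Notch signalling (1.20 ± 0.15; 2 higher adjusted over the list alone, 4 called with the block). Their list was called in camera (adjusted p = 0.0249) but not with an estimated correlation (adjusted p = 0.468), without negative 5 (0.0548), positive 2 (0.0662) or the 4 libraries numbered 6 and 7 (0.154). It turned to lower with the marker scores (0.0808), in a fit whose group term is poorly determined.

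Among other endocrine markers, those of delta cells were higher. Sst, the delta cell hormone somatostatin (chromosome 16, 23889573 to 23890958), rose from 181 ± 128 to 1088 ± 578 CPM (SD, n = 7 each; log2 fold change 2.58 ± 0.51, SE, adjusted p = 0.00562). The delta cell transcription factor Hhex rose with 2.50 ± 0.45 (adjusted p = 0.00202), and both did so in all 7 pairs. Of 6 delta cell markers 2 rose and 4 were not called (3 higher adjusted over the list alone), among them Rbp4 (1.06, adjusted p = 0.13; 0.0444 without positive 3) and Frzb (−0.25, adjusted p = 0.239). Their list rose in camera (adjusted p = 0.0326), not with an estimated correlation (adjusted p = 0.355) or without the 4 libraries numbered 6 and 7 (adjusted p = 0.0601). It turned to lower with the marker scores (adjusted p = 0.391), in a fit whose group term is poorly determined. With the block 3 were higher, now with Pdyn (0.74 ± 0.47, adjusted p = 0.406; 0.000121 with the block, in all 7 pairs). Hhex is also expressed in endothelial cells, whose markers rose. Of 14 alpha cell markers 0 were called (0 adjusted over the list alone; Peg3 with the block), with Gcg, the hormone glucagon, at 17640 ± 7414 and 12220 ± 8042 CPM (−0.53 ± 0.42, adjusted p = 0.516). Their list was called lower in camera (adjusted p = 0.0212), but not with an estimated correlation (adjusted p = 0.468), the block (adjusted p = 0.0925) or without negative 1 (0.0642). Of 4 PP cell markers 0 were called over all genes (1 lower adjusted over the list alone and with the block, Fxyd6, at −0.20 ± 0.07, adjusted p = 0.0783, 0.00689 with the block, lower in all 7 pairs), and Ppy, the hormone pancreatic polypeptide, was at 1461 ± 620 and 1833 ± 796 CPM (0.33 ± 0.34, adjusted p = 0.633).

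Of 28 acinar markers, 7 fell, 0 rose and 21 were not called (9 lower adjusted over the list alone), with a median log2 fold change of −1.65. Pnlip, pancreatic lipase (chromosome 19, 58652498 to 58681788), fell from 77.1 ± 67.1 to 6.57 ± 8.40 CPM and its cofactor Clps from 18.3 ± 14.8 to 1.52 ± 2.08 CPM (SD, n = 7 each), both lower in all 7 pairs. Rnase1 fell with −2.04 ± 0.45 (SE). The most abundant members were not called, with Ctrb1, a chymotrypsinogen, at 193 ± 172 and 100 ± 155 CPM (−0.94 ± 0.90, adjusted p = 0.605; 0.028 with the block). Prss2, a trypsinogen of a family whose members share reads, was at 68.7 ± 57.4 and 32.5 ± 48.4 CPM (−1.08 ± 0.85, adjusted p = 0.519; 0.0298 with the block). Without positive 1, which had 440 CPM of Ctrb1 against 11.4 to 100 in the other positive libraries, Ctrb1 was at −2.16 and Prss2 at −2.24 (adjusted p = 0.132 and 0.0935). The list fell in camera (adjusted p = 8.81e-11) but not with an estimated correlation (adjusted p = 0.465), and 22 members fell with the block. Acinar RNA varied widely within groups, from 18.3 to 194 CPM of Pnlip in negative and from 0.565 to 24.8 in positive libraries. The ratio of Ctrb1 to Pnlip, chosen after these values were seen, was 1.72 to 4.0 in negative and 6.11 to 26.9 in positive libraries, with no overlap.

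**Figure D4:**
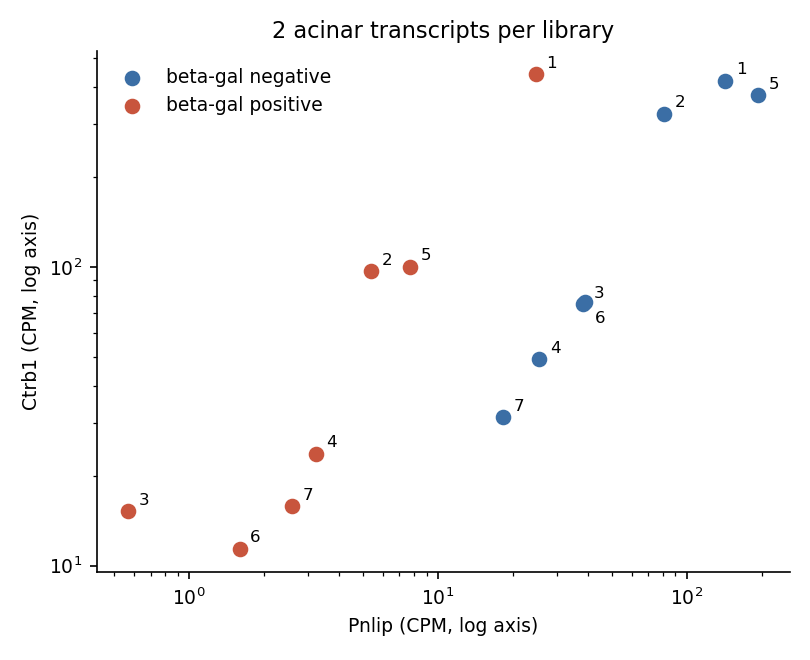
CPM of Pnlip (x axis) and of Ctrb1 (y axis), both on log axes, in each of the 14 libraries, with the replicate number beside each point. Positive libraries lay to the left of the negative ones at like levels of Ctrb1, as in pair 1, where Ctrb1 was at 419 and 440 CPM in negative and positive cells and Pnlip at 143 and 24.8.

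Of 58 lysosomal genes, 8 rose, 1 fell and 49 were not called (8 higher and 1 lower adjusted over the list alone; 12 and 3 with the block). The rises with the smallest p were those of Acp5 (log2 fold change 6.17), the cathepsin Ctsh (2.20), the lipase Lipa (1.63) and Grn, progranulin (0.50), genes that macrophages express strongly. The cathepsin Ctsf fell (−0.30). The list was called in camera (adjusted p = 0.0139, median 0.08), but not with an estimated correlation (adjusted p = 0.51) or without positive 6 (adjusted p = 0.0502), the library with the highest macrophage score, or all 4 libraries numbered 6 and 7 (0.124). It turned to lower with the marker scores (0.137), in a fit whose group term is poorly determined. Of 25 autophagy genes 1 rose, Optn (0.35; 1 adjusted over the list alone, 3 called with the block), a call lost without negative 2 (0.0564) or positive 6 (0.0604), and the list did not change (adjusted p = 0.694).

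Of 24 genes of TGF-beta and BMP signalling, 11 rose, 1 fell and 12 were not called (13 higher and 2 lower adjusted over the list alone; median log2 fold change 0.50). The inhibitory Smad6 rose with 4.59 ± 0.44, Inhbb, a subunit of activin B, with 4.14 ± 0.74, the receptor Tgfbr2 with 2.68 ± 0.45 and Smad3 with 2.06 ± 0.23 (SE), all in 7 of 7 pairs. The activin receptor Acvr1c fell (−0.55 ± 0.16, adjusted p = 0.0447), a call lost without negative 2, 4, 5 or 6 or positive 2, 3, 6 or 7 (0.0583 to 0.0904). The list rose in camera (adjusted p = 1.57e-08), not with an estimated correlation (adjusted p = 0.116). With the macrophage and endothelial marker scores as covariates it was still called higher (adjusted p = 0.0131, median 0.50), with 0 members called. The group term of the fit with these scores is poorly determined, so it cannot decide whether RNA of such cells raised the list. Smad6, Inhbb, Tgfbr2 and Smad3 were highest in positive 6 and 7, where macrophage and endothelial markers were highest too. Inhbb was at 48.7 and 33.5 CPM there and at 5.09 to 15.9 CPM in the other positive libraries. Of 31 interferon response genes 5 rose and 0 fell (7 higher adjusted over the list alone). The smallest p among them belonged to B2m, the light chain of class I antigen presentation (1.36 ± 0.21), Ifit3 (1.52 ± 0.26) and Ifit2 (4.41 ± 0.76). The interferon list had an adjusted p of 0.00509 and an adjusted p of 0.611 with an estimated correlation. Without the libraries numbered 6 and 7 it was not called (adjusted p = 0.305), and with the marker scores it was called lower (adjusted p = 3.07e-09), both added after the data were seen. Ifit2 was at 52.4 and 42.7 CPM in positive 6 and 7 and at 3.44 to 12.4 CPM in the other positive libraries. Of 30 antioxidant genes 5 rose and 1 fell (6 higher and 1 lower adjusted over the list alone). The master regulator Nfe2l2 rose with 0.52 ± 0.09, heme oxygenase Hmox1 from 349 ± 65.7 to 592 ± 143 CPM (0.76 ± 0.15) and catalase, Cat, with 1.58 ± 0.33. Txnip, a glucose-induced inhibitor of thioredoxin, fell from 366 ± 80.3 to 222 ± 31.4 CPM (−0.72 ± 0.13, adjusted p = 0.00169), and each of these changes was seen in 7 of 7 pairs. The antioxidant list was called higher in camera (adjusted p = 0.0123), not with an estimated correlation (adjusted p = 0.468) or without the 4 libraries numbered 6 and 7 (adjusted p = 0.305).

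Of 32 cell cycle genes 2 rose, Mcm3, a replication licensing factor (2.71 ± 0.37), and Ube2c (0.87 ± 0.24, adjusted p = 0.0309), the second lost without negative 1, 4, 6 or 7 or positive 2, 5, 6 or 7 (0.0518 to 0.0711), and 0 fell (2 higher adjusted over the list alone, 4 with the block). The list rose in camera (adjusted p = 0.000824), not with an estimated correlation (adjusted p = 0.468) or without the 4 libraries numbered 6 and 7 (adjusted p = 0.083). Mcm3 was highest in positive 6 and 7 (11.6 and 10.2 CPM), where macrophage and endothelial markers were highest too. With their scores as covariates the list was called higher (adjusted p = 0.00751, median 0.46 against 0.25, 0 members called). The group term of that fit is poorly determined, so it cannot decide whether RNA of such cells raised the list. All mitochondrially encoded genes together, not only those of messenger RNAs, took 1.39 ± 0.21% of negative and 1.85 ± 0.47% of positive counts (SD, n = 7 each). Of 13 mitochondrially encoded messenger RNAs measured, 3 rose, mt-Nd3, mt-Nd4l and mt-Nd6 (0.59, 0.87 and 0.97; 4 adjusted over the list alone, 6 with the block). This list rose in camera (adjusted p = 0.00198), not with an estimated correlation (adjusted p = 0.468). The call of mt-Nd3 was lost without negative 1 or 4 or positive 7 (0.0527 to 0.0605). That of mt-Nd4l was lost without negative 2, 3, 5 or 7 or positive 2, 3, 4, 5 or 6 (0.0503 to 0.0885), and that of mt-Nd6 without any library but negative 3 and positive 1 and 2 (0.0558 to 0.101). The strand setting of the counting was not given in the sources used here, so mt-Nd6, which lies on the other strand from mt-Nd5, could share reads with its neighbours. Of 28 cilium genes 3 fell and 0 rose, Bbs2 (−0.27 ± 0.06), Ift80 (−0.30 ± 0.08) and Tctn1 (−0.23 ± 0.06), in all 7 pairs (3 lower adjusted over the list alone). Cilium genes fell in camera (adjusted p = 0.0152), not with an estimated correlation (adjusted p = 0.292) or without the 4 libraries numbered 6 and 7 (adjusted p = 0.101). The call was lost for Ift80 without positive 3 (0.0592) or 6 (0.0504) and for Tctn1 without negative 7 (0.0517) or positive 3, 4 or 6 (0.0652, 0.0577 and 0.0606).

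Cholesterol synthesis genes (24 measured, 0 called over all genes or adjusted over the list alone, 1 higher and 5 lower with the block) and replication-dependent histones (26 measured, 0 called, 0 adjusted over the list alone, 1 higher and 2 lower with the block) fell as lists in camera (adjusted p = 0.0123 and 0.0143). Their medians were −0.12 and −0.21, and they were not called with an estimated correlation (adjusted p = 0.468 for each), and the histones not without negative 2 (0.0802) or positive 5 (0.074), nor cholesterol synthesis genes without the 4 libraries numbered 6 and 7 (0.101). The libraries were made from polyadenylated RNA, to which most such histone transcripts contribute little. Unfolded protein response genes (32 measured, 0 called, 0 adjusted over the list alone) and glycolysis genes (21 measured, 2 higher, Slc2a1 at 0.57 and Hk1 at 1.54; 2 adjusted over the list alone) were not called as lists (adjusted p = 0.0693 and 0.101). Both were called higher with the block (adjusted p = 0.0311 and 0.00386), with 7 higher members of the first and 11 higher and 2 lower of the second, but not with an estimated correlation beside the block (adjusted p = 0.742 and 0.369). Single removals also called them, the first without negative 7 (0.0381) or positive 2 (0.0112) or 4 (0.0461), the second without negative 1 (0.00873) or positive 3 (0.0448) or 4 (0.04525).

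The remaining lists were not called in camera. Of 30 collagens 5 rose and 2 fell (5 and 3 adjusted over the list alone; adjusted p = 0.8, 0.01265 without negative 3). The rises included the basement membrane collagens Col4a1 (2.75), Col4a2 (3.88) and Col18a1 (2.79) and also Col13a1 (4.94) and Col25a1 (1.61), and the falls were Col28a1 (−0.79) and Col6a6 (−0.57; lost without any library but negative 3 and positive 4 and 5, 0.0514 to 0.0921). The median was −0.28 and the mean −0.08, while camera's direction was up. Of 23 insulin and IGF signalling genes Igf2bp2 (0.98) and Grb10 (0.31, a call lost without any single library but negative 3 and positive 5, 0.0515 to 0.134) rose (2 adjusted over the list alone, 7 with the block; list adjusted p = 0.126, 0.0322 without positive 2). Of 15 regulators of apoptosis of the BCL2 family Bcl2l11 (0.40) and Pmaip1 rose (2 adjusted over the list alone, 4 called with the block; list adjusted p = 0.129, 0.0205 with fry). Of 28 immediate early and dissociation stress genes Ier3 rose (1.53; 1 adjusted over the list alone, 4 called with the block; list adjusted p = 0.801). Of 25 TCA cycle genes Cs, citrate synthase, rose (0.24; 1 adjusted over the list alone, 4 with the block; list adjusted p = 0.672), a call lost without negative 2, 4 or 5 or positive 6 or 7 (0.0579 to 0.0686). Of 75 nuclear respiratory chain subunits Atp5b (0.21) and Cox5a (0.26) rose and Atp5l fell (−0.46), with 0 adjusted over the list alone, 7 with the block and a list adjusted p of 0.8. Atp5b lost its call without negative 2 to 6 or positive 1, 5, 6 or 7 (0.06 to 0.117), and Cox5a without any library but negative 7 and positive 3 and 4 (0.0515 to 0.112). Of 84 cytosolic ribosomal proteins, 74 mitochondrial ribosomal proteins and 37 proteasome subunits 0 were called over all genes or adjusted over the list alone (3, 3 and 1 with the block; list adjusted p = 0.75, 0.696 and 0.672).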

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

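Single libraries that stood apart from the other 6 of their group were sought among 28 genes (12 named in advance and the 16 largest changes), the mean log2 CPM of 36 lists, depth, the share of the 20 highest genes and the mitochondrial share, 134 groups of 7 in all. In 7 of them the gap to the nearest library, as a share of the range, passed Dixon's limit for 7 samples; chance alone passes it in about 1 of 20. No explanation of these 7 values was tested.

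Negative 3 stood high in 4 lists. Its mean log2 CPM was 4.54 for stellate cell, pericyte and fibroblast markers (−0.1 to 1.77 in the other 6), 4.84 for p53 targets (4.49 to 4.63), 2.04 for cell cycle genes (0.76 to 1.24) and 3.95 for regulators of apoptosis of the BCL2 family (3.51 to 3.7). Without this library the count of lower genes was 616, against 266 with it. The transcription factor Pdx1 was highest in both libraries numbered 1, at 6.98 log2 CPM in negative cells (4.65 to 5.65 in the others) and 6.34 in positive cells (4.8 to 5.36). Trp53 was lowest in negative 1, at 4.62 log2 CPM (5.18 to 5.48 in the others).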

How the results depend on the processing

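The settings without libraries 6 and 7 and with marker scores were chosen after the data were seen, as was the block together with an estimated correlation. Of the 203 genes held by the naming rule, 114 were called, and the block kept all 114 and called 44 of the other 89. DESeq2 size factors and library size only each lost 2, voom with sample weights lost 1 and called 10 more, and DESeq2's Wald test lost 0 and called 19 more. In these settings and without any 1 library, no such gene changed direction where either fit called it. The 1313 calls went to 3200 with the replicate block (1930 higher, 1270 lower; 1043 of the 1047 higher and all 266 lower calls were among them), 581 without libraries 6 and 7 (536 higher, 45 lower) and 1 with the marker scores (1 higher, 0 lower; 484 at an unadjusted p below 0.05). Other settings gave 1151 to 1755, with 499 lower genes under DESeq2's Wald test. Leaving out 1 library gave 965 to 1883 genes, 825 to 1267 higher and 140 to 616 lower, and 19 to 24 lists. Of 22 called lists, camera kept 0 with an estimated correlation (6 had an unadjusted p below 0.05) 2 with the block as well, 12 without libraries 6 and 7 and 19 with the block, which called 21 in all. The fry test, which sets a list against no change and not against other genes, called 13, 12 of the 22 and also the BCL2 family (0.0205). It lost lysosomal genes (0.0527), acinar markers (0.0535), NF-kappaB targets (0.065), progenitor genes (0.0702), mitochondrially encoded messenger RNAs (0.0703), stellate cell, pericyte and fibroblast markers (0.0743), cholesterol synthesis (0.103), alpha cell markers (0.121), interferon response genes (0.134) and histones (0.134). The block lost senescence effectors, p53 targets and alpha cell markers, gained the unfolded protein response and glycolysis, and changed no other list call. Without libraries 6 and 7 camera lost senescence effectors (0.222), progenitor genes (0.154), delta cell markers (0.0601), lysosomal genes (0.124), p53 targets (0.382), antioxidant genes (0.305), cell cycle genes (0.083), interferon response genes (0.305), cholesterol synthesis (0.101) and cilium genes (0.101). With the marker scores camera called 13 lists, and of the 22, 5 kept their call and direction, 6 lost the call and 11 changed direction. Those kept were mitochondrially encoded messenger RNAs (adjusted p = 3.88e-11), cell cycle genes (0.00751), p53 targets (0.012), TGF-beta and BMP genes (0.0131) and histones (0.0131). Those lost were alpha cell markers (0.133), cilium genes (0.133), cholesterol synthesis (0.137), senescence effectors (0.288), stellate cell, pericyte and fibroblast markers (0.49) and disallowed genes (0.827). The lists that turned from higher to lower were interferon response genes (adjusted p = 3.07e-09), NF-kappaB targets (0.0161), progenitor genes (0.0808), lysosomal genes (0.137), delta cell markers (0.391), secretory phenotype factors (0.484) and antioxidant genes (0.49), and also endothelial (0.391) and macrophage markers (0.44), which make up the scores. Acinar markers (0.00751) and beta cell identity genes (0.49) turned from lower to higher. Of the 14 lists not called before, proteasome subunits (0.00288), glycolysis (0.0115) and unfolded protein response genes (0.0131) turned to lower, while immediate early genes (3.07e-09) and insulin and IGF signalling genes (0.0104) were called higher. The 2 scores accounted for 86.7% of the variance of the group label itself (positive or negative), so the group term of this fit is poorly determined. For the other changes the cause was not tested. In simulated counts, 49.5% of 1.5-fold changes were found.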

Other observations

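The 5 lists of the first 2 paragraphs, the count of pairs with less acinar RNA and the fit of all lists with the marker scores were chosen after the data were seen. The other tests were set before their results were seen. Positive cells were rich in transcripts of the basement membrane, the sheet of matrix under endothelium and around islet capillaries. Of 17 measured genes, 12 rose and 0 fell (13 higher and 1 lower adjusted over the list alone), among them Nid2 (log2 fold change 4.72 ± 0.64, SE), Lamb1 (3.97 ± 0.51), Col4a1 (2.75 ± 0.37) and Lama3 (2.69 ± 0.38), each in 7 of 7 pairs. The list adjusted p was 3.89e-17 in camera and 0.0951 with an estimated correlation, beside a median rise of 4.85 in endothelial markers. Of 7 genes tied to the aryl hydrocarbon receptor, Cyp1a1 (6.91) and the receptor itself, Ahr (0.63 ± 0.12), rose (2 adjusted over the list alone), while its other targets Tiparp (0.07), Nqo1 (0.43) and Cyp1b1 (−1.11) were not called. Their list had an adjusted p of 0.0263, 0.0692 with the block, and an adjusted p of 0.0951 with an estimated correlation. Cyp1a1 was at 33.6 to 154 CPM in the positive libraries, highest in positive 2 (endothelial score 5.06 log2 CPM) and at 86.9 and 89.9 CPM in positive 6 and 7, which had the highest endothelial scores (5.55 and 5.45). In negative cells it was highest in libraries 6 and 7, at 1.27 and 1.85 CPM, which had the highest endothelial scores of their group (1.71 and 1.55).

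Of 14 genes of iron storage and heme breakdown, 3 rose and 11 were not called. The 3 were the ferritin chains Ftl1 (0.47 ± 0.09) and Fth1 (0.77 ± 0.21) and Hmox1 (0.76 ± 0.15), in all 7 pairs (4 adjusted over the list alone, 7 with the block; list adjusted p = 0.0023, adjusted p = 0.0951 with an estimated correlation). Fth1 lost its call without negative 1, 2, 4, 5, 6 or 7 or positive 7 (0.0543 to 0.0771). It was at 1112.9 and 887.75 CPM in positive 6 and 7, the libraries with the highest macrophage scores (5.17 and 4.66 log2 CPM), and at 412 to 491 CPM in the other positive libraries. Ferritin genes have many processed pseudogenes that can share reads. Of 20 cytosolic aminoacyl-tRNA synthetases, Iars (0.35 ± 0.08) and Rars (0.38 ± 0.10) rose, 5 did adjusted over the list alone and 9 with the block (list adjusted p = 0.0023, adjusted p = 0.31 with an estimated correlation). Rars lost its call without negative 2, 4 or 5 or positive 6 or 7 (0.0517 to 0.07). Imprinted genes, which are expressed from 1 parental copy, went both ways. Of 34, 5 were higher, such as Mest (2.71 ± 0.46) and Dlk1 (1.61 ± 0.18), and 3 were lower, such as Nap1l5 (−0.73 ± 0.11) (6 and 3 adjusted over the list alone, 6 and 7 with the block). As a list they did not change (adjusted p = 0.2805).

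The number of called genes was set against other splits of the libraries. Among 100 splits into 7 and 7, the real one included, 1 gave as many genes as the real 1313, the real one itself. The next gave 1140 and was the real split with 1 library exchanged each way, while another split of that kind gave 0. Among the 64 splits that part all 7 pairs, 1 gave as many as the real 3200 with the block, again the real one. The next, with 1 pair turned round, gave 843, and the others with 1 pair turned round gave 0 or 1. Only the real split reached its count, 1 of 100 and 1 of 64, the smallest shares that these splits could give. Chance assignment of the libraries is thus unlikely for both counts, but not excluded.

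The rise of the secretory phenotype list may come from RNA of macrophages and endothelial cells among the positive cells. Within groups, its 39 members correlated with the mean of both marker scores at a median of 0.61, at percentile 100 of 10000 random lists matched on expression (median 0.05, 95th percentile 0.17). The random lists were drawn gene by gene, so other lists of genes that vary together could also stand above them. Both scores were highest within their groups in the libraries numbered 6 and 7. Any other difference of these libraries would thus correlate alike, and the test cannot tell it from such RNA. Whether endocrine cells also expressed the secretory factors cannot be told apart from RNA of macrophages and endothelial cells: with both scores as covariates 0 members were called, and the list mean was −0.11 (95% interval −1.59 to 1.37) against 2.29 without them. This came with a loss of precision, since the scores accounted for 86.7% of the variance of the group label and the median error per gene grew 2.78 times. The labels name no gate against other cell types, and whether such cells carry the enzyme activity themselves was not tested.

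The fall of beta cell genes could come from dilution of beta cell RNA by that of other cells. This would lower all of them by 1 ratio if the other cells expressed none of them. The tables argue against 1 shared ratio, since 10 of the 48 members differed from the list's median paired ratio of −0.24 at an adjusted p below 0.05. Of these, 6 lay below it, Mafa (−0.76), Mlxipl (−0.72), Insrr (−0.66), Gipr (−0.52), Trpm5 (−0.48) and Nkx6-1 (−0.39), and 4 above it, Stx1a, Chgb, Scg2 and Vamp2, which other endocrine or neural cells express as well. With the marker scores as covariates the list turned to higher (adjusted p = 0.49, median 0.07, 0 members called), in a fit whose group term is poorly determined. Dilution by cells that express some of the members would also give unequal ratios, so the test cannot exclude it. Such dilution, another mix of endocrine cells and a lower level within beta cells stay open, the last as an untested hypothesis.

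The fall of acinar genes might reflect 1 pool of acinar RNA that was smaller in the positive libraries, or carryover into single negative libraries. The first as the whole cause is argued against by 14 of 28 members that differed from the list's median paired ratio of −2.0, with 7 above and 7 below it. Against the second, the acinar score was lower in the positive library in 7 of 7 pairs, by −1.95 ± 0.67 log2 CPM (SD, n = 7). With the marker scores as covariates the list turned to higher (adjusted p = 0.00751, median 2.21, 0 members called), in a fit where the scores accounted for 86.7% of the variance of the group label. A smaller amount of acinar RNA of another makeup and a basal level of single members in other cells stay open, and no biological explanation was tested.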
